A study of Mus musculus with 9 samples.

How the data were processed

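The series holds 9 mouse samples on the Illumina MouseWG-6 v2.0 expression array, a platform on which beads carrying 1 probe each read the amount of labelled RNA bound. Per the labels, 3 samples are wild-type thymus, 3 are thymus of mice carrying an Lmo2 transgene and 3 are cell lines grown from leukaemias of such mice, all on the C57BL/6 background, and about 300 ng of total RNA (RNeasy Mini Kit) was labelled for each array. The cell lines carry the numbers 3, 175 and 261 in the labels and are called lines 1, 2 and 3 here. Groups and replicate numbers were taken from the sample titles. The titles of the thymus samples each carry a different number, but the labels do not say that these stand for separate animals. The p-values therefore measure the spread between these samples. For the lines this is a spread between differently numbered lines, and for thymus it may be partly technical. No slide or scan information was used, because none is given in the sources used here.

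The deposited non-normalized table gives, per the file headers, a probe intensity and a detection p-value for each of 45281 probes on each array. The intensity values were read as not scaled between arrays, since their medians differ, and as not background-subtracted, since 0 values are negative, the lowest is 86.0 and undetected probes have medians of 111.5 to 151.9. Control probes are not used here. The deposited normalized table holds log2 intensities with nearly equal distributions on all arrays, and the series' own value table holds the same log2 numbers, with a largest difference of 0 over 45281 probes. BeadStudio and limma are named in the submitters' processing notes, and their versions, functions and settings are not given in the sources used here. The direction of the log2 table follows from its match to the intensities: the normalization used here and the authors' log2 table correlated at r = 0.999 over all probes. Values here minus the authors' had a median of -0.10 on each array over all probes, and of -0.35 to -0.34 over the tested genes.

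Starting from the non-normalized table, intensities were background-corrected, quantile-normalized and log2-transformed with neqc in limma 3.58.1 under R 4.3.3, which estimates background from the detection p-values and adds an offset of 16. A probe was kept where its detection p-value was under 0.05 on at least 3 of the 9 arrays, which left 19490 probes. Gene names came from the platform annotation: 34885 probes have 1 symbol, 18 have several and 10378 have none. Symbols were checked through their Entrez identifiers against a RefSeq gene table, in which 34807 annotation entries matched and 0 symbols changed. Each gene was represented by the kept probe with the highest mean over all 9 arrays, giving 10072 genes, of which 4088 had more than 1 kept probe. The 3199 kept probes without a single symbol were set aside from the comparisons. No genome was used here, so no positions are given.

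Each of the 3 comparisons was fitted in limma (lmFit and eBayes) on its own 6 arrays, without covariates, two-sided, and a gene was called changed where the Benjamini-Hochberg adjusted p was under 0.05. The words rose, fell and changed are used only of such calls, and values are log2 fold changes with their standard errors. Before the data were examined, 22 gene lists were fixed, 15 of processes and stages in T cells and leukaemia and 7 of markers of other cell types that a thymus or a culture could hold, together with the comparisons, the tests and most alternatives. The lists are partners of the LMO2 complex, stem and early T progenitor genes, Notch targets and pre-TCR stage genes, double-positive thymocyte genes, mature T cell genes, T cell receptor (TCR) signalling genes, cell cycle genes, MYC targets and ribosome biogenesis, T cell leukaemia tumour suppressors, p53 targets, the BCL2 family, glycolysis, cholesterol synthesis, the interferon response, immediate early and heat shock genes, and markers of NK and cytotoxic cells, B cells, macrophages and granulocytes, MHC class II antigen-presenting cells, thymic epithelium, fibroblasts and endothelium, and erythroid cells. Lmo2 is in no list. Lists with at least 5 measured genes, 20 of the 22, were tested with camera in limma at the preset inter-gene correlation of 0.01, adjusted over the 20 lists, with an estimated correlation and fry as alternatives.

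Genes were named by a rule fixed beforehand. It takes Lmo2, the 6 largest increases and 6 largest decreases per comparison among called genes whose groups do not overlap, which are detected on all 3 arrays of the higher group and whose symbol is not a clone or predicted name, then up to 2 called members of each list, or up to 2 with the smallest p where none was called, and list members that differ by more than 2 log2 units among the cell lines. It also allows any measured member of the first 2 lists to be named, and not all of these are named here. Where a count of at most 5 list members holds further genes, these are named as well and were chosen after their values were seen, as were Xist, Eif2s3y, Cd4, Cd8a, Hspa1a, Dntt, C1qb, C1qc, Csf1r, S100a9, and the members of the additional lists of the closing section. Where a gene's represented probe was detected on no array of its dimmer group, the change is given as at least N-fold: the mean of the brighter group was set against the mean, over the dimmer group's arrays, of the higher of the lowest log2 value among detected probes and the probe's own value.

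The fit and the list test were tested on simulated data with the real genes' means and spreads. For labelled transgenic against wild-type thymus, 22% of 100 genes changed by 1 log2 unit and 81% of 100 genes changed by 2 were recovered, with 10 false calls among 113. For cell lines against wild-type thymus these shares were 25% and 70%, with 11 false calls among 106, and for cell lines against labelled transgenic thymus 6% and 44%, with 12 among 62. The shifted list was called in all 3 comparisons, and of 19 unshifted lists 1 was called for labelled transgenic against wild-type thymus and 0 in either other comparison. The simulated genes varied independently, so the list test was not tried on genes that vary together. Real lists can do so, with estimated correlations of 0.41 for NK and 0.47 for MHC class II markers between the thymus groups. The 3 arrays per group therefore limit the precision, and a change of 1 log2 unit was mostly missed in the simulated data. In each comparison the simulated share of false calls was above the threshold set for the adjusted p. It was highest for cell lines against labelled transgenic thymus, with 12 among 62. The real calls may therefore hold more false ones than that threshold states, but the simulation cannot give their share. It was 1 data set per comparison, with spreads taken from 3 arrays and fewer changed genes than were called in the real data.

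The alternatives were no background correction, an offset of 50, scaling to a common median, the authors' normalized table, a detection p-value under 0.01, no detection filter, the mean of a gene's probes, a minimum log2 change of 1, all 9 arrays in 1 fit, a trended and robust variance prior, array weights, the replicate number as a block, and leaving out each array in turn. After the data were seen, a term for sex as read from Xist and Y-linked genes, the omission of X- and Y-linked genes, and the omission of other cell types' markers were added. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.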

Results

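The series measured gene expression in thymus and in leukaemia cell lines of mice that express the transcriptional cofactor Lmo2 in T cells from a CD2 promoter, and its title concerns whether leukaemias started by Lmo2 still need it once established. LMO2 joins DNA-binding proteins such as LYL1, TAL1 and GATA factors to LDB1 and is normally switched off as thymocytes commit to the T lineage. The 9 arrays comprised 3 of wild-type thymus, 3 labelled Lmo2 transgenic thymus and 3 of cell lines. Median raw intensity ranged from 118.5 to 161.2 over the arrays, and between 35.0% and 43.0% of probes were detected, with the cell lines at the low end of both. Over the 10072 genes tested, wild-type arrays correlated with each other at r between 0.978 and 0.992, labelled transgenic arrays at 0.944 to 0.967, and cell lines at 0.912 to 0.940. Wild-type and labelled transgenic arrays correlated at 0.921 to 0.962, and cell lines with wild-type arrays at 0.847 to 0.871. Cd4 and Cd8a were near background on the thymus arrays, where Cd8a was detected by neither of its probes, while Cd8b1 was detected by all 3 of its probes, and Rag1 (10.72 ± 0.18 SD in wild type, n = 3) and Kit (9.74 ± 0.50) were well above it. Whether thymocytes were sorted before RNA extraction is not given in the sources used here, so which thymus cells the arrays represent is open.

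Lmo2 itself was read by 1 probe, and it went against the label. Its log2 intensity was 8.06 ± 0.14 (SD, n = 3) in wild-type thymus, 6.20 ± 0.76 on the arrays labelled transgenic and 4.53 ± 0.29 in the cell lines, where it was not detected. It fell by 1.86 ± 0.36 (SE) between wild-type and labelled transgenic thymus (limma adjusted p = 0.0325). Between wild-type thymus and the cell lines it fell at least 6.63-fold (adjusted p = 8.96e-05), and between labelled transgenic thymus and the cell lines at least 1.83-fold (adjusted p = 0.0381). Whether the probe reads the transgene's message was not analysed here, and an exchange of labels was not excluded, so the group is called labelled transgenic throughout. The call in thymus was lost under 2 planned settings, at adjusted p = 0.0687 with no detection filter and 0.0691 with the replicate number as a block, and without wild-type array 1, 2 or 3 or labelled transgenic array 2 (0.0579 to 0.144). The call between labelled transgenic thymus and the lines was lost with no background correction, an offset of 50, no filter or the replicate block (adjusted p = 0.0623 to 0.0679). In the leave-one-out fits it was kept only without labelled transgenic array 3.

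The first comparison, labelled transgenic against wild-type thymus, addresses what the transgene changes in the thymus. Several regulators of early blood progenitors were far higher on the labelled transgenic arrays. Lyl1, a helix-loop-helix partner of LMO2, rose by 3.60 ± 0.43 log2 units and the homeobox gene Hhex by 3.50 ± 0.24. Nfe2, a basic leucine zipper factor of megakaryocyte and red cell development, rose by 3.23 ± 0.27. Other progenitor genes were lower, among them the homeobox gene Hoxa7, which fell at least 13.2-fold (adjusted p = 0.000726). Markers of NK cells and of MHC class II antigen-presenting cells were lower on the same arrays, although these list calls were lost with an estimated correlation (adjusted p = 0.352 with an estimated correlation for both). In all, 471 of 10072 genes changed in limma, 231 upward and 240 downward, and 435 of them by at least 1 log2 unit.

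The largest increases were in Tbx4, a T-box factor of limb and lung development (at least 34.7-fold, adjusted p = 0.0061), Rpl3l, a ribosomal protein of striated muscle (5.17 ± 0.34), and Igf2bp3, a foetal RNA-binding protein (5.10 ± 0.32). Next came the peroxisomal oxidase Acox2 (5.06 ± 0.47), the receptor Gpr34 (4.84 ± 0.44) and the lipocalin Lcn4 (4.75 ± 0.53), with adjusted p between 0.000726 and 0.0061. The largest decreases were in Trbv13-1, a TCR beta variable segment (-4.45 ± 0.44), Hoxa7, Zfp518b (at least 7.70-fold), the NK receptor genes Klra3 (-3.37 ± 0.41) and Klra10 (-3.36 ± 0.38), and the gap junction gene Gja1 (-3.28 ± 0.26), with adjusted p between 0.000726 and 0.00513. The 3 arrays of 1 group all lay above those of the other for 22.3% of the genes, where chance gives 10%. Of the 191 changed genes with more than 1 kept probe, 80 had another probe called in the same direction and 0 had one called in the opposite direction.

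Stem and early T progenitor genes divided: 3 of 9 measured rose and 4 fell (adjusted over the list alone, 4 and 4). Lyl1, Hhex and Nfe2 rose. Hoxa7 fell with Bcl11a (-2.43 ± 0.44, adjusted p = 0.0239), Mef2c (-1.98 ± 0.43, adjusted p = 0.0465, lost in 11 of 20 other settings) and the adhesion receptor Cd44 (-1.34 ± 0.23, adjusted p = 0.0207). Kit, the stem cell factor receptor, differed by 1.95 ± 0.56 and was not called (adjusted p = 0.12), and Bmi1 differed by 0.21 ± 0.18. The list as a whole did not shift (adjusted p = 0.718). Among 11 measured partners of the LMO2 complex, Lyl1 was the 1 member that rose and none fell (adjusted over the list alone, 2 and 1; list adjusted p = 0.551). Ldb1 differed by -0.21 ± 0.23, Runx1 by 0.20 ± 0.26, Tcf12 by 0.52 ± 0.20, Cbfa2t3 by 0.74 ± 0.21 and Tcf4 by -0.67 ± 0.19.

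T-lineage lists showed few calls. Of 12 Notch and pre-TCR stage genes, the mTOR inhibitor Deptor rose (2.16 ± 0.40) and Ptcra, the pre-TCR alpha chain, fell (-2.43 ± 0.41), also when adjusted over the list alone (list adjusted p = 0.749). Of 13 double-positive thymocyte genes 0 rose and 3 fell (adjusted over the list alone, 1 and 4), namely Cd8b1 (-2.61 ± 0.34), the recombinase gene Rag1 (-1.54 ± 0.21) and Ets2 (-1.23 ± 0.23), and the list was not called (adjusted p = 0.675). The probes of Cd8b1 disagreed, the other 2 giving 0.24 and -3.21. In the TCR signalling list of 13, the costimulatory receptor Cd28 fell (-2.31 ± 0.47; adjusted over the list alone, 0 rose and 2 fell; list adjusted p = 0.718). No mature T cell gene of 13 was called (1 rose and 1 fell over the list alone; list adjusted p = 0.874). In the double-positive and TCR lists the medians were above 0 (0.23 and 0.03) while the means (-0.23 and -0.31) and tests pointed down, and in the mature T cell list the median (0.16) and test pointed up and the mean (-0.10) down.

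Markers of NK and cytotoxic cells fell as a list, with 8 of 12 members down and 0 up (adjusted over the list alone, 10 and 0) and a median of -1.65 (adjusted p = 1.25e-09; adjusted p = 0.352 with an estimated correlation). The chemokine Ccl5 (-2.62 ± 0.41) and the receptor Klrd1 (-2.48 ± 0.38) led them. Of 10 MHC class II cell markers 5 fell and 0 rose (adjusted over the list alone, 9 and 0), with a median of -1.91 (adjusted p = 2.06e-08; adjusted p = 0.352 with an estimated correlation). The 5 were H2-DMa (-2.59 ± 0.43), the class II transactivator Ciita (-2.17 ± 0.38), H2-Aa (-2.15 ± 0.44), H2-DMb1 (-1.86 ± 0.32) and Siglech (-1.55 ± 0.29). The 7 B cell markers shifted down (median -0.84, adjusted p = 0.00668; adjusted p = 0.502 with an estimated correlation) without a called member (0 rose and 1 fell over the list alone). Of 13 macrophage and granulocyte markers Mpo (-2.44 ± 0.30) and Mpeg1 (-2.15 ± 0.29) fell and the list did not shift (1 rose and 2 fell over the list alone; adjusted p = 0.718). Fibroblast and endothelial markers were not called (5 measured, median 0.68, 0 called, 1 rose over the list alone, adjusted p = 0.298). The tight junction gene Cldn4 fell (-1.82 ± 0.25) among 4 thymic epithelial markers, and neither of the 2 measured erythroid markers was called (Hba-a1 2.25 ± 0.88, adjusted p = 0.253; Rhag 0.23 ± 0.19).

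MYC targets and ribosome biogenesis genes shifted down without a called member (15 measured, median -0.39, adjusted p = 6.95e-04; adjusted p = 0.352 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, lay closest at -0.73 ± 0.16 (adjusted p = 0.0543). Glycolysis genes shifted down in the same way (11 measured, median -0.37, adjusted p = 0.0189; adjusted p = 0.411 with an estimated correlation). The glycolysis call was lost in 4 of 18 other settings (highest adjusted p = 0.364). Over the list alone 0 of the glycolysis genes and 1 of the MYC targets fell. Among 12 T cell leukaemia tumour suppressors Cdkn2a, which encodes inhibitors of the cell cycle and of MDM2, rose at least 1.92-fold (adjusted p = 0.0155, its other 2 probes giving 0.22 and 0.78), as did Etv6 (1.25 ± 0.28, adjusted p = 0.0497). Etv6 lost its call in 14 of 20 other settings, and 0 members fell, also over the list alone (list adjusted p = 0.709). The cell cycle inhibitor Cdkn1a fell (-2.70 ± 0.36) among 10 p53 targets (3 rose and 1 fell over the list alone; list adjusted p = 0.199). No member of the cell cycle (17 measured), BCL2 (10), cholesterol synthesis (10), interferon (11) or immediate early (10) lists was called, and 0 over the list alone except for 1 immediate early gene that rose, with the lists at adjusted p of 0.0633, 0.675, 0.624, 0.551 and 0.199.

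Of the 5 lists called, all downward, none held with an estimated correlation, and NK markers, MHC class II markers and glycolysis held by fry (adjusted p = 0.0456 each). Xist, the transcript of the inactive X chromosome, read 12.66 and 11.37 on labelled transgenic arrays 1 and 2 and was at background by the same probe on array 3 and in wild type (4.38 to 4.49). Y-linked Eif2s3y read 9.44 to 10.12 on those 4 arrays and was not detected on the other 2. A fit with a term for this difference leaves labelled transgenic array 3 alone to be set against wild type. Its calls therefore rest on 1 array and are not given, and Lmo2 had a log2 fold change of -2.63 in it. Leaving out wild-type array 1, 2 or 3 gave 213, 154 or 171 genes. Of 43 named genes and called list members, 15 kept their calls in every setting. Ets2 lost its call in 9 of 20 settings, Cd28 in 8, Deptor in 7 and Ptcra and Cd44 in 6 each, and H2-Aa in 8 of 19.

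**Figure D1:**
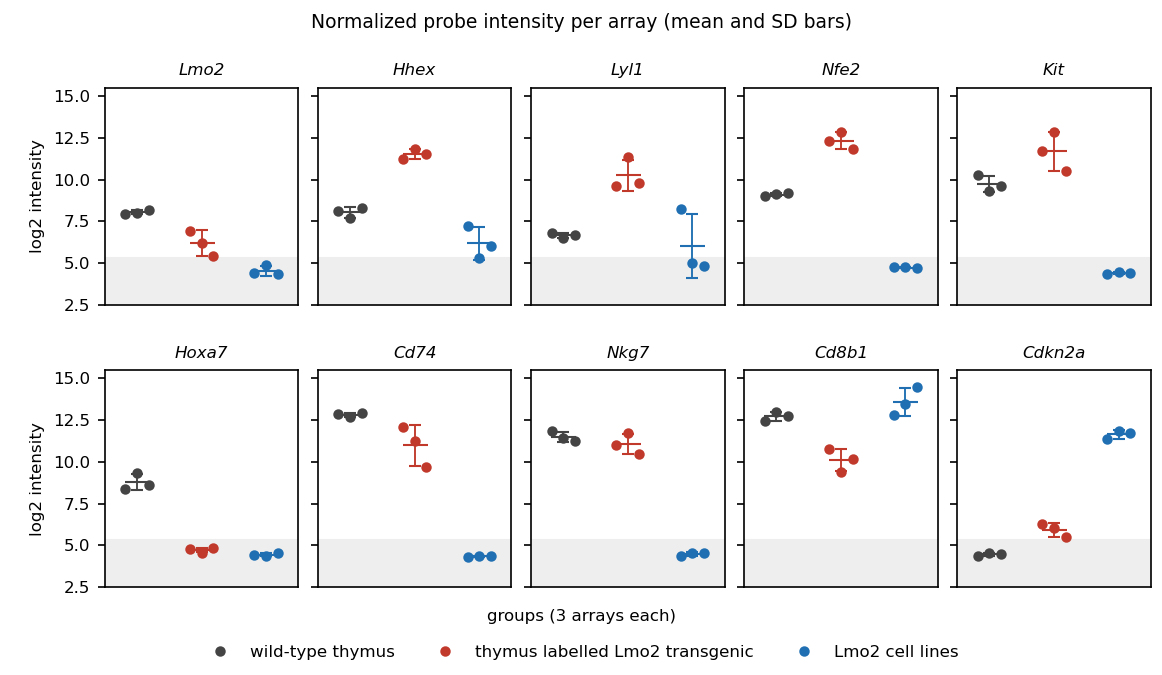
Log2 probe intensity per array for 10 genes in wild-type thymus, thymus labelled Lmo2 transgenic and the Lmo2 cell lines (dots, 3 arrays per group), with bars for the mean and SD and a grey band reaching up to the highest of the arrays' lowest detected values. Lmo2 averaged 8.06, 6.20 and 4.53 in the 3 groups, Nfe2 was highest in labelled transgenic thymus at 12.33 and lowest in the lines at 4.73, and Cdkn2a reached 11.65 in the lines.

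The second comparison set the leukaemia cell lines against wild-type thymus and changed far more genes: 2469 of 10072 in limma, 1219 upward and 1250 downward. Of these, 1704 changed by at least 1 log2 unit, 738 of them upward. Cdkn2a, often lost in T cell leukaemia, was higher in all 3 lines, at least 102-fold (adjusted p = 7.89e-06). Genes of early progenitors, of mature T cells and of NK, myeloid, B and MHC class II cells were lower, in many cases down to background. Genes of cholesterol synthesis were higher. The list calls for progenitor genes, B cell markers and cholesterol synthesis were lost with an estimated correlation (adjusted p = 0.0532, 0.186 and 0.212). Leaving out wild-type array 1, 2 or 3 gave 1585, 1160 or 9.7e+02 (rounded) changed genes, and the replicate block 1396. The groups did not overlap for 46.2% of the genes, where chance gives 10%.

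After Cdkn2a the largest increases were in Fam183b (5.35 ± 0.37), the cytoskeletal adaptor Pdlim4 (5.33 ± 0.55), the matrix protein gene Fbln1 (5.12 ± 0.33), the stress-induced pseudokinase Trib3 (at least 25.8-fold) and the glutathione-degrading enzyme Chac1 (at least 22.5-fold), with adjusted p between 0.000118 and 0.0123. The largest decreases were in Trgv4, a TCR gamma variable segment (at least 214-fold), the MHC class II invariant chain Cd74 (at least 181-fold), lysozyme Lyz1 (at least 86.8-fold), the cytotoxic granule gene Nkg7 (at least 72.5-fold), Klra3 (at least 66.9-fold) and H2-Eb1 (at least 64.8-fold), with adjusted p between 2.74e-06 and 1.43e-05. Of 1034 changed genes with more than 1 kept probe, 598 had another probe called the same way and 34 had one called the opposite way.

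Of 9 stem and early T progenitor genes 6 fell and 0 rose (also over the list alone), with a list adjusted p of 1.61e-05 (adjusted p = 0.0532 with an estimated correlation) and a median of -3.06, or -2.90 with undetected genes at their bound. Kit (at least 21.3-fold), Nfe2 (at least 13.7-fold), Hoxa7 (at least 10.9-fold), Bcl11a (at least 8.19-fold) and Mef2c (at least 6.49-fold) were not detected in any line, and Hhex fell by 1.84 ± 0.49. Cd44 (-2.90 ± 1.37, adjusted p = 0.162) and Lyl1 (-0.65 ± 0.86, adjusted p = 0.601) differed between the lines and were not called. Of 11 partners of the LMO2 complex, the corepressor Cbfa2t2 rose (1.30 ± 0.17) and 3 fell, Tcf4 (-1.63 ± 0.40), Runx1 (-1.54 ± 0.33) and Ldb1 (-0.86 ± 0.22), also over the list alone, without a shift of the list (adjusted p = 0.344). The other probe of Runx1 gave -0.03 and that of Cbfa2t2 1.72.

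Mature T cell genes fell, 8 of 13 down and 0 up (adjusted over the list alone, 10 and 0; median -2.82; adjusted p = 3.95e-05, and adjusted p = 0.0473 with an estimated correlation). The survival gene Bcl2 (at least 18.5-fold) and the interleukin 7 receptor Il7r (-4.82 ± 1.09) led them. In the TCR signalling list 5 of 13 fell and 0 rose (adjusted over the list alone, 7 and 0; median -0.91; adjusted p = 0.00266, and adjusted p = 0.0781 with an estimated correlation). The changes were small, in Lcp2 (-1.05 ± 0.31), Rasgrp1 (-0.99 ± 0.22), Ptprc (-0.94 ± 0.21), Cd3g (-0.89 ± 0.21) and Cd3e (-0.85 ± 0.17). Il2ra (-4.35 ± 0.52), Bcl11b (-1.26 ± 0.21) and Deptor (-1.06 ± 0.21) fell among 12 Notch and pre-TCR stage genes (0 rose; the same counts over the list alone; list adjusted p = 0.0775). Cd1d1 (-1.11 ± 0.28), Themis (-1.10 ± 0.32) and Cd24a (at least 1.45-fold) fell among 13 double-positive genes (0 rose; 1 rose and 3 fell over the list alone; list adjusted p = 0.393).

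Cholesterol synthesis was the 1 list that shifted up: 7 of 10 genes rose and 0 fell, also over the list alone (median 1.06; adjusted p = 0.00238, and adjusted p = 0.212 with an estimated correlation). Lanosterol synthase Lss rose by 1.63 ± 0.21 and Cyp51 by 1.58 ± 0.21. Interferon response genes shifted down, 5 of 11 falling and 0 rising, also over the list alone (median -0.62, or -0.56 at the bound; adjusted p = 0.00196, and adjusted p = 0.0781 with an estimated correlation). The 5 were Gbp2 (-3.81 ± 0.63), Oasl2 (at least 6.28-fold), Ifit3 (-2.95 ± 0.23), Usp18 (-2.66 ± 0.77) and Irf7 (at least 1.48-fold). Immediate early and heat shock genes also shifted down, 5 of 10 falling and 0 rising (adjusted over the list alone, 6 and 0; median -1.32, or -1.01 at the bound; adjusted p = 0.00238, and adjusted p = 0.341 with an estimated correlation). The 5 were Egr1 (-4.11 ± 0.26), Junb (-2.29 ± 0.51), Hspa1a (at least 1.81-fold), Zfp36 (-1.47 ± 0.19) and Jun (-1.17 ± 0.25).

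Cell cycle genes rose in part, 6 of 17 up and 0 down, also over the list alone, without a list call (median 0.32, adjusted p = 0.0826, and 0.0481 by fry), Ccne1 by 1.39 ± 0.26 and Birc5 by 0.98 ± 0.22. Among 12 tumour suppressors Cdkn2a and Cdkn2b (at least 2.00-fold) rose and Runx1 and Bcl11b fell, with the same counts over the list alone. Camera gave no shift of the list (adjusted p = 0.994), while fry called it upward (adjusted p = 8.47e-04). The stress gene Sesn2 rose (2.22 ± 0.35, its other probe giving 0.38) among 10 p53 targets, where 0 fell, also over the list alone, and the median (-0.13) and mean (0.12) differed in sign (adjusted p = 0.841). The proapoptotic Bad rose (0.96 ± 0.24) and Bcl2 fell in the BCL2 family of 10 (the same counts over the list alone; adjusted p = 0.54). Aldoa (1.14 ± 0.24) and Pkm (0.66 ± 0.17) rose and 0 fell among 11 glycolysis genes, also over the list alone (adjusted p = 0.477). Ncl fell (-0.73 ± 0.18) and 0 rose among 15 MYC targets (0 called over the list alone; adjusted p = 0.54).

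Of 42 measured markers of other blood cells 30 were not detected in any line, while 7 were detected in all 3, among them Cst3 (11.44) and Ebf1 (5.66). NK and cytotoxic markers fell in 10 of 12 cases (median -2.90, or -2.48 at the bound; adjusted p = 5.96e-10) and MHC class II markers in 8 of 10 (median -3.57, or -3.06 at the bound; adjusted p = 3.66e-09), each with adjusted p = 0.0389 with an estimated correlation. Macrophage and granulocyte markers fell in 10 of 13 (median -1.03, or -0.62 at the bound; adjusted p = 1.56e-06, and adjusted p = 0.0389 with an estimated correlation). In these 3 lists 0 rose, and the counts were the same over the list alone. Klrd1 fell at least 37.4-fold and Lyz2 at least 28.1-fold. Of 7 B cell markers 5 fell and 0 rose (adjusted over the list alone, 6 and 0; median -1.44, or -0.85 at the bound; adjusted p = 4.59e-04, and adjusted p = 0.186 with an estimated correlation). The 5 were Cd79b (at least 40.0-fold), Fcrla (at least 13.5-fold), Cd22 (at least 3.5-fold), Bank1 (at least 1.4-fold) and Ms4a1 (at least 1.32-fold). Fibroblast and endothelial markers were not called (5 measured, 0 called, also over the list alone; median -0.21 and mean 0.27; adjusted p = 0.799). Cldn4 fell (at least 2.47-fold) and the thymic chemokine Ccl25 rose (1.65 ± 0.49) among thymic epithelial markers, and erythroid Rhag rose by 0.77 ± 0.20. Without the markers of other cell types 2412 genes changed.

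The calls for mature T cell genes and for NK, macrophage and MHC class II markers held with an estimated correlation, 4 of the 10 called lists. By fry 12 lists were called, all of these 10 among them (adjusted p at most 0.0119). Of 103 named genes and called list members 54 kept their calls in every setting. Hspa1a lost its call in 11 of 18 settings, Lcp2 in 10 of 18, Rhag in 10 of 16 and Ccl25 in 9 of 17. Among the macrophage and granulocyte markers C1qb lost its call in 12 of 17 settings, C1qc in 11, Csf1r in 10 and S100a9 in 9. Cd24a, Themis, Usp18 and Pkm lost theirs in 8 of 18, Bank1 in 8 of 16 and Ms4a1 in 8 of 17, and the other probe of Pkm gave -0.29. Scaling to a common median put the median log2 fold change of all genes at 0.27, against 0.08 here, and gave 3331 changed genes with 67.0% upward, against 49.4% upward here, and ended the call of the TCR signalling list (adjusted p = 0.139).

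**Figure D2:**
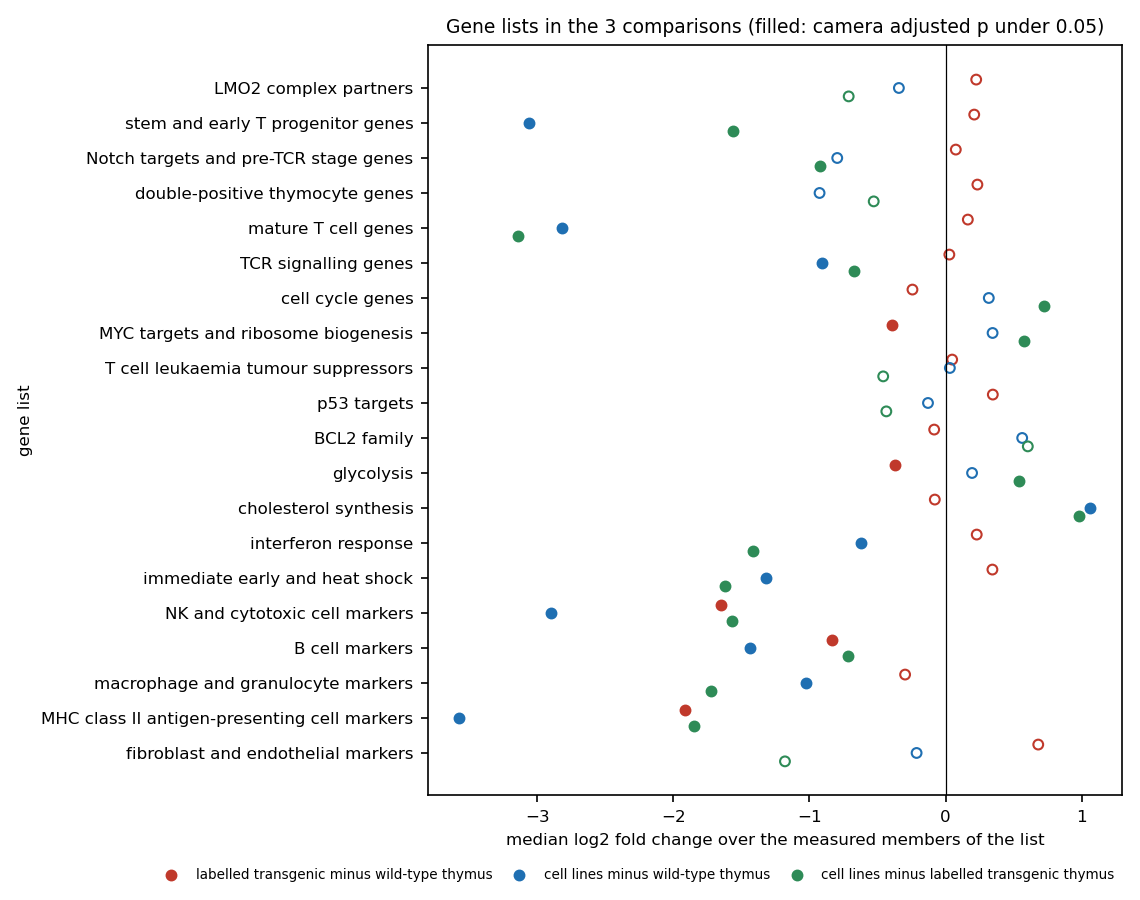
Median log2 fold change of the measured members of each of the 20 tested gene lists (horizontal axis, log2 units; 1 line per list) in the 3 comparisons, with filled circles for lists called by camera at the preset correlation and open circles for the others. Cell lines against wild-type thymus reached -3.57 for MHC class II markers and 1.06 for cholesterol synthesis, while labelled transgenic against wild-type thymus reached -1.91 and -1.65 for MHC class II and NK markers.

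The third comparison, cell lines against labelled transgenic thymus, addresses what the lines kept of the transgenic state. Progenitor genes that were high in labelled transgenic thymus were lower in the lines. Nfe2 fell at least 129-fold (adjusted p = 0.000107), Kit at least 82.4-fold (adjusted p = 0.00101), Hhex by 5.34 ± 0.49 log2 units (adjusted p = 0.00194) and Lyl1 also (-4.25 ± 0.96, adjusted p = 0.0313). Nfe2 and Kit were not detected in any line, whereas Lyl1 was detected in line 1 (8.22) and Hhex in lines 1 and 3 (7.25 and 6.05). The Lyl1 call was lost in 7 of 18 other settings (highest adjusted p = 0.0921). In limma 1579 genes changed, 728 upward and 851 downward, 603 and 779 of these by at least 1 log2 unit. The groups did not overlap for 42.4% of genes against 10% by chance. In the simulated data 12 of 62 calls in this comparison were false. The real calls may hold more false ones than the threshold states, but 1 simulated data set with fewer changed genes cannot give their share. The cell cycle and cholesterol lists shifted up in the lines, with adjusted p = 0.398 and 0.224 with an estimated correlation. The lists of NK, MHC class II, macrophage and B cell markers shifted down, with adjusted p between 0.224 and 0.398 with an estimated correlation.

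The largest increases were in Pdlim4 (6.57 ± 0.62), Cdkn2a (5.72 ± 0.28), the muscle cytochrome oxidase subunit Cox6a2 (5.50 ± 0.65), Chac1 (at least 21.5-fold), the neutral amino acid transporter Slc1a4 (at least 19.1-fold) and Trib3 (4.27 ± 0.42), with adjusted p between 0.000227 and 0.0177. The largest decreases were in the mast cell protease Cpa3 (at least 391-fold), Trgv4 (at least 212-fold), the thrombin receptor F2r (-8.02 ± 0.53), Nfe2, Lyz1 (at least 95.6-fold) and Cd93 (at least 117-fold), with adjusted p between 4.08e-05 and 0.00112. Of 712 changed genes with more than 1 kept probe, 372 had another probe called the same way and 11 had one called the opposite way.

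Of 9 stem and early T progenitor genes the 4 just named fell and 0 rose, also over the list alone (median -1.56; adjusted p = 1.98e-04, and adjusted p = 0.224 with an estimated correlation). Among the LMO2 partners Lyl1, Runx1 (-1.75 ± 0.39) and Cbfa2t3 (-1.06 ± 0.24) fell and 0 rose (adjusted over the list alone, 2 rose and 4 fell; list adjusted p = 0.0751). The other probe of Runx1 gave -0.13 and that of Cbfa2t3 -0.50. Mature T cell genes fell in 7 of 13 cases (0 rose; adjusted over the list alone, 0 and 9; median -3.14; adjusted p = 1.98e-04, and adjusted p = 0.224 with an estimated correlation), with Il7r at -4.98 ± 1.12 and Gimap6 at -4.77 ± 0.74. Lcp2 (-1.48 ± 0.26), Rasgrp1 (-1.25 ± 0.25), Cd3e (-0.88 ± 0.20) and Lat (-0.80 ± 0.20) fell in the TCR list (0 rose; the same counts over the list alone; adjusted p = 0.0365, and adjusted p = 0.224 with an estimated correlation). In the Notch list Il2ra (-4.92 ± 0.60), Deptor (-3.22 ± 0.45) and Bcl11b (-1.05 ± 0.26) fell (0 rose; the same counts over the list alone; adjusted p = 0.0396, and adjusted p = 0.224 with an estimated correlation). Other settings ended the Notch call in 8 of 17 cases and the TCR call in 6 of 17 (highest adjusted p = 0.291 and 0.346). Of the double-positive genes Cd8b1 rose (3.47 ± 0.50, its other probes giving -1.15 and 4.49) and Cd1d1 (-1.53 ± 0.30), Themis (-1.38 ± 0.33) and Cd24a (at least 1.71-fold) fell, also over the list alone (list adjusted p = 0.307).

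Cholesterol synthesis genes rose in 5 of 10 cases with 0 falling (adjusted over the list alone, 7 and 0; median 0.98; adjusted p = 0.00144, and adjusted p = 0.224 with an estimated correlation). They were Lss (2.10 ± 0.27), Mvd (1.92 ± 0.42), Cyp51 (1.68 ± 0.26), Fdps (1.37 ± 0.27) and Msmo1 (1.21 ± 0.29). Cell cycle genes shifted up, with Ccne1 (1.99 ± 0.29), Cdc20 (1.11 ± 0.28) and Aurka (0.97 ± 0.23) rising and 0 falling of 17 (adjusted over the list alone, 4 and 0; median 0.72; adjusted p = 0.0052, and adjusted p = 0.398 with an estimated correlation). MYC targets shifted up without a called member, also over the list alone (median 0.58; adjusted p = 0.0249, and adjusted p = 0.401 with an estimated correlation). Glycolysis also shifted up, with Aldoa (1.40 ± 0.34) and Pkm (1.21 ± 0.20) rising and 0 falling, also over the list alone (median 0.54; adjusted p = 0.0458, and adjusted p = 0.43 with an estimated correlation). Interferon genes fell in 4 of 11 cases (0 rose; adjusted over the list alone, 0 and 5; median -1.42, or -0.98 at the bound; adjusted p = 0.00355, and adjusted p = 0.398 with an estimated correlation). These were Gbp2 (-3.73 ± 0.68), Oasl2 (at least 6.21-fold), Irf7 (at least 2.09-fold) and Rtp4 (at least 1.54-fold). Immediate early genes fell in 5 of 10 (0 rose; adjusted over the list alone, 0 and 6; adjusted p = 7.13e-04, and adjusted p = 0.257 with an estimated correlation). These were Egr1 (-3.23 ± 0.39), Junb (-2.49 ± 0.53), Dusp1 (-2.06 ± 0.31), Jun (-1.66 ± 0.42) and Zfp36 (-1.58 ± 0.20).

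In the remaining lists of T cells, Cdkn2a rose and Runx1 and Bcl11b fell among tumour suppressors (4 and 4 over the list alone; median -0.46 and mean 0.21; adjusted p = 0.827). Sesn2 rose (at least 3.97-fold) and Phlda3 (-1.78 ± 0.43) and Tnfrsf10b (-1.55 ± 0.38) fell among p53 targets (1 and 3 over the list alone; adjusted p = 0.297). The other probe of Sesn2 gave 0.09 and that of Phlda3 -1.84. Bcl2 fell (at least 10.6-fold) with 0 rising in its family, also over the list alone (adjusted p = 0.297). Markers of other cells fell as lists, and 0 rose in any of them. NK markers fell in 6 of 12 cases (adjusted p = 1.98e-04, and adjusted p = 0.261 with an estimated correlation). MHC class II markers fell in 5 of 10 (adjusted p = 1.98e-04, and adjusted p = 0.224 with an estimated correlation), and macrophage markers in 6 of 13 (adjusted p = 1.80e-04, and adjusted p = 0.224 with an estimated correlation). B cell markers fell in 2 of 7 (adjusted p = 0.0305, and adjusted p = 0.398 with an estimated correlation). Over the list alone 7, 5, 11 and 3 fell. Their medians were -1.57, -1.84, -1.72 and -0.72, or -1.01, -1.16, -1.11 and -0.01 at the bound, so for B cell markers little of the median was above what the arrays can read. Nkg7 fell at least 54.0-fold, Cd74 at least 51.1-fold, Lyz2 at least 29.9-fold, Cd79b at least 17.2-fold and Fcrla at least 3.95-fold. Fibroblast and endothelial, thymic epithelial and erythroid markers had 0 called members, with 2 fibroblast and endothelial markers falling over the list alone (adjusted p = 0.408). None of the 14 called lists, 4 of them upward, held with an estimated correlation. The estimate for the TCR and Notch lists lay below the preset 0.01 (-0.037 and -0.017). By fry 12 lists were called, and of the 14 the cell cycle, MYC, glycolysis and interferon calls were lost (adjusted p = 0.0551 to 0.0733). Fry also called the LMO2 partners downward (adjusted p = 0.00833) and the tumour suppressors upward (adjusted p = 0.0382), which camera did not. Other settings ended the glycolysis and B cell calls in 5 of 17 cases each (highest adjusted p = 0.291 and 0.0839), and the MYC call was lost without line 1 (adjusted p = 0.131). Of 76 named genes and called list members 37 kept their calls in every setting. Fcrla lost its call in 10 of 17 settings, Jun in 9 of 18, and Lat, Themis, Cbfa2t3, Bcl11b, Cd24a and Cd3e in 8 of 18 each. The other probe of Pkm gave -0.08 and that of Siglech 0.17. Leaving out labelled transgenic array 1, 2 or 3 gave 444, 797 or 948 changed genes, and leaving out line 2 or 3 gave 667 or 926.

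The comparisons with wild-type thymus share their controls. Of the 240 genes that fell in labelled transgenic thymus 156 also fell in the lines and 6 rose, and of the 231 that rose 37 also rose and 34 fell. Leaving out wild-type array 1, 2 or 3 cut the shared falling genes to 60, 43 or 48 and the shared rising genes to 16, 13 or 13. The replicate block gave 99 and 23, array weights gave 79 rising in both, and leaving out line 1 gave 60 rising in both. Independent lists of the full sizes would share 29.8 falling and 28.0 rising genes. Fold changes correlated across genes at r = 0.29, against 0.21 (0.18 to 0.25) in 100 simulations of unchanged groups set against the same controls, and their covariance was 0.201 against 0.0304, a difference of 0.171. The 3 controls cannot be parted into groups of at least 2 arrays each, and part of the excess may come from the shared arrays. Against labelled transgenic thymus, 104 of the 231 genes that had risen there fell in the lines and 3 rose. These genes were chosen for high values on the same labelled transgenic arrays, which favours a fall in advance, so this count decides nothing. Over all 10072 genes 851 fell and 728 rose in that comparison, and against wild-type thymus 34 of the 231 fell. Hoxa7 and Klra3 were among the genes lower in both comparisons with wild type, and Hhex and Nfe2 among those that rose in labelled transgenic thymus and fell in the lines.

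The 3 cell lines differed from each other, and with 1 array per line these differences have no replicate check. Among 41 members of the first 3 lists and the tumour suppressor list, 9 differed by more than 2 log2 units, and for 8 of them line 1 stood apart. Notch1 read 4.95 in line 1, at background, against 11.17 and 11.02 in lines 2 and 3. The same held for Notch3 (4.86 against 9.53 and 9.68), the Notch targets Dtx1 (4.79 against 9.67 and 9.55) and Hes1 (4.55 against 8.44 and 9.59), and Ptcra (4.93 against 11.08 and 10.46). Lyl1 (8.22 against 4.99 and 4.82) and Cd44 (9.85 against 4.50 and 4.59) were detected in line 1 alone. Lef1 read 7.52, 9.84 and 8.84, and Nrarp, another Notch target, 7.53, 9.38 and 4.69. Y-linked Eif2s3y was detected in line 1 (9.56) and in neither other line, and Xist weakly in line 2 (5.47). The recombinase gene Rag1 and the terminal transferase Dntt were also at background in line 1 (4.88 and 4.72), against 10.97 and 10.83 in line 2. Lines 1 and 2 differed by more than 2 log2 units in 524 genes, lines 1 and 3 in 565 and lines 2 and 3 in 343. The median SD per gene was 0.326 among the lines, 0.316 among labelled transgenic and 0.210 among wild-type arrays.

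**Figure D3:**
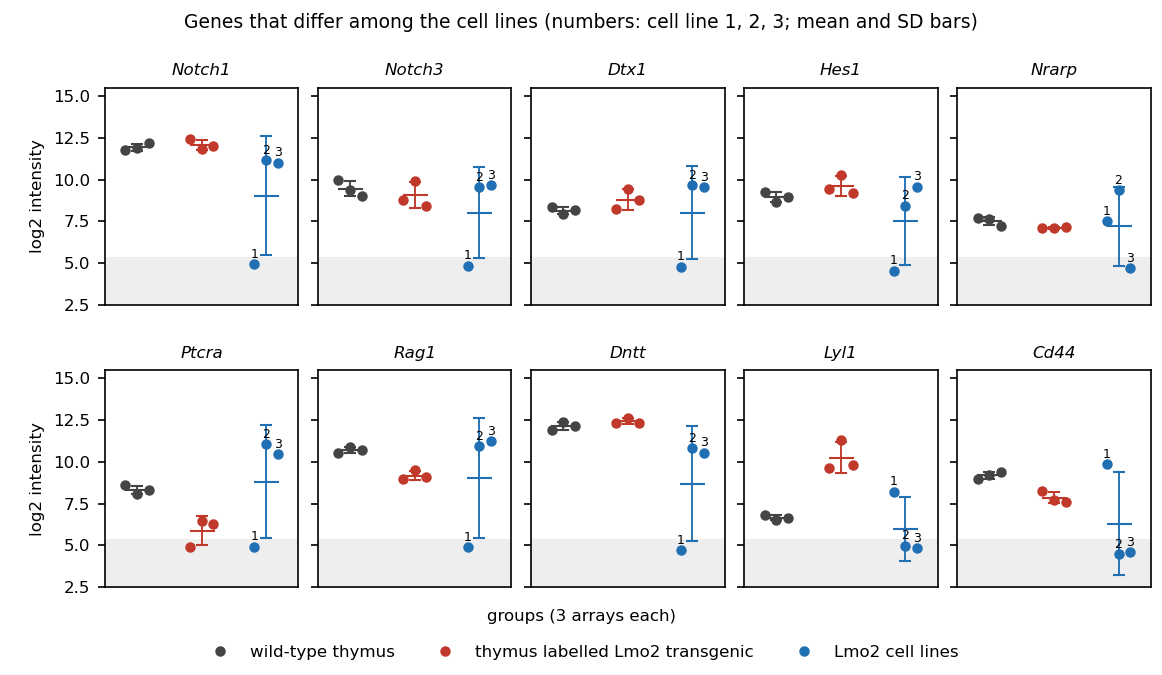
Log2 probe intensity per array (dots, 3 per group, the cell lines marked 1, 2 and 3) for 10 genes that differ among the cell lines, with bars for the mean and SD and a grey band reaching up to the highest of the arrays' lowest detected values. Notch1 in line 1 (4.95) lies in the band while lines 2 and 3 (11.17 and 11.02) lie near the thymus arrays, and Lyl1 and Cd44 show the opposite order.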

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

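The tests of exchanged labels, of normalization, of the probe, of RNA quality, of sex with separate controls and of the NK and MHC class II markers were chosen only after their results had been seen, while the first sex test on held-out genes and the splits were fixed before they were run. Among the 3199 measured probes without a single gene name, 77 changed between labelled transgenic and wild-type thymus (18 higher, 59 lower), 1084 between cell lines and wild-type thymus (367 and 717) and 633 between cell lines and labelled transgenic thymus (200 and 433). What these probes read was not analysed here.

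The Lmo2 probe was lower on the arrays labelled transgenic. Whether labels were exchanged stays open: Hhex, Lyl1, Nfe2 and Kit had a median log2 fold change of 3.37 (median SE 0.35, 3 of the 4 called), but they were picked after their values were seen, and the whole progenitor list, in which 4 genes fell, had a median of 0.21 (adjusted p = 0.718). Normalization is no likely cause, as the fall was at least 0.99 log2 units under 5 normalizations (log2 fold change -0.99) and the lowest raw wild-type intensity, 335.3, was above the highest labelled transgenic one, 266.1. The gene has 1 probe, and a transgene lacking that probe's target, with a lower endogenous message, may explain the fall, but the test cannot tell because probe and transgene sequences were not used here. A PCR reading of transgene and endogenous transcripts apart would settle it.

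The genes changed between labelled transgenic and wild-type thymus could partly follow sex, since Xist was high on labelled transgenic arrays 1 and 2 (12.66 and 11.37) and at background by the same probe on the other thymus arrays. Values go against sex as the whole cause but rest on the 1 labelled transgenic array with low Xist, so sex stays open: 94.7% of 453 autosomal genes called from arrays 1 and 2 moved the same way on array 3, with a median shift of 1.59 against 1.75 log2 units, and with different wild-type arrays for the calls (80 to 214 genes) and for the shift at least 93.9% did, by a median of at least 1.96. Labelled transgenic array 2, where the heat shock gene Hspa1a read 9.47 against 4.43 and 4.59, is not the main source of the calls. Without that array 454 genes were called, 368 of them shared (78.1%). No measure of RNA quality was used here, so RNA quality as a cause was not tested. Only 1 of 10 splits of the 6 arrays called as many genes, the real one with 471 against at most 0. The same held for cell lines against wild-type thymus (1 of 10; 2469 against at most 0) and against labelled transgenic thymus (1 of 10; 1579 against at most 1), and 10 splits cannot give a share under 0.05.

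NK and MHC class II markers were lower in labelled transgenic thymus, which might reflect a smaller share of all non-T cells alike. Against other cells' markers detected in wild type, the difference of medians was -1.29 (permutation p = 0.0165 over 1e+05 resamples, 21 members against 15), which passed the threshold. After this was seen a second version left out members near background, giving -0.72 (permutation p = 0.0785, 20 members against 9). Both versions shuffled genes between the sets as if they varied independently. The estimated correlations were 0.41 for NK and 0.47 for MHC class II markers. These p-values can therefore be too small, and they do not measure the spread between samples. With the versions at odds the question stays open, and the other markers also had less room to fall, at a median of 2.40 against 4.82 log2 units above background. Of these other markers 11 of 15 were lower, and 7 of the 9 in the second version. All 5 measured fibroblast and endothelial markers together had a median of 0.68. Both sets held only members detected on all 3 wild-type arrays, which leaves out markers seen only in labelled transgenic thymus. Sex also stays open: all 22 of 22 members lay below the wild-type mean on labelled transgenic array 3, with a median log2 difference of -2.51, but this is 1 array. Many of these genes, Ccl5 and Klrd1 (10.36 and 10.55 in wild type) among them, can also be expressed by T cells, and thymocytes sorted free of NK and antigen-presenting cells would remove such a source.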

How the results depend on the processing

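The sex term, the omission of X- and Y-linked genes and the omission of other cells' markers were chosen only after the results had been seen, and the other settings were fixed before. Over all settings 3361 gene results stayed the same and 646 were weaker, 989 list results stayed the same, 31 were weaker and 17 stronger, and 0 reversed. Of 222 named or called gene results 106 were kept in every setting. The cause of the differences was not tested.

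With an estimated correlation 0 lists were called for labelled transgenic against wild-type thymus, 4 for cell lines against wild-type thymus and 0 for cell lines against labelled transgenic thymus, in place of 5, 10 and 14. The estimate was high for some lists, as for MHC class II markers between the thymus groups (0.47). For others it lay below the preset 0.01, as for TCR genes in cell lines against wild-type thymus (-5.1e-04) and against labelled transgenic thymus (-0.037). A higher correlation cannot have ended those calls. A call lost with an estimated correlation therefore does not by itself show that the genes of a list vary together. By fry, 3, 12 and 12 lists were called in the 3 comparisons. The sex term gave 3 lists and 308 changed genes in the first comparison, against 471 without it. All 9 arrays in 1 fit gave 300 changed genes in the first comparison and 2794 between cell lines and labelled transgenic thymus, against 1579. Array weights raised the genes rising in both comparisons with wild type from 37 to 79.

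The Lmo2 call in thymus was lost with no filter on dim probes (-1.86, adjusted p = 0.0687). Between cell lines and labelled transgenic thymus it was lost with no background correction (-0.62, adjusted p = 0.0679), with an offset of 50 (-0.94, adjusted p = 0.0652) and with no filter (-1.67, adjusted p = 0.0649). The median SD among the cell lines, 0.326, became 0.211 with no background correction, 0.269 with an offset of 50 and 0.185 with no filter.

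The replicate block, which treats equal replicate numbers as a pairing, gave 293, 1396 and 651 changed genes and 99 falling and 23 rising in both comparisons with wild type. Lmo2 kept its values of -1.86 (adjusted p = 0.0691) and -1.67 (adjusted p = 0.0623) without a call. Deviations of equally numbered arrays correlated at r between -0.15 and 0.16, so the numbers gave no sign of a pairing.

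Leaving out 1 array at a time gave 154 to 549 changed genes for labelled transgenic against wild-type thymus (213, 154 and 171 without wild-type arrays 1, 2 and 3), 9.7e+02 (rounded) to 2978 for cell lines against wild-type thymus (1585, 1160 and 9.7e+02 without wild-type arrays 1, 2 and 3) and 444 to 1459 for cell lines against labelled transgenic thymus (444, 797 and 948 without labelled transgenic arrays 1, 2 and 3, and 667 and 926 without lines 2 and 3). Called lists numbered 4 to 7, 10 to 11 and 9 to 15, with 9 lists without line 1. Lmo2 ranged from -2.23 to -1.47, from -3.69 to -3.43 and from -2.05 to -1.29, its call in the third comparison kept only without labelled transgenic array 3. Genes falling in both comparisons with wild type numbered 43 to 195 (60, 43 and 48 without wild-type arrays 1, 2 and 3) and rising in both 13 to 60 (16, 13 and 13 without these, 60 without line 1). A slide block was not run, as slides are not given in the sources used here.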

Other observations

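The lists of ATF4 targets and tRNA synthetases were chosen after the large increases of Trib3 and Chac1 had been seen but before either was tested, and the test of the Notch list in line 1 was chosen only after its result had been seen. Beyond the fixed lists, Hoxa5 fell with Hoxa7 in labelled transgenic thymus (at least 3.30-fold, adjusted p = 0.00194), while Hoxa4 differed by -0.24 ± 0.32. Of 16 measured genes of the Klr receptor family 0 rose and 10 fell there, among them Klra1 (-2.50 ± 0.27), Klra16 (-2.59 ± 0.41) and Klra7 (-2.57 ± 0.53). The other 6, such as Klrk1 (-1.38 ± 0.38, adjusted p = 0.106), were not called. The Hoxa and Klr families were picked after their values had been seen. Klrb1c, Klrd1 and Klrk1 also belong to the NK list, so the Klr count is not separate from that result. Tbx4 and Rpl3l, among the largest increases in labelled transgenic thymus, read 10.31 and 9.71 in line 1 and were at background in lines 2 and 3 (4.52 and 4.55 for Tbx4).

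A raised ATF4 programme, the response to amino acid shortage, may lie behind several of the largest increases in the cell lines. Of 15 measured ATF4 targets 8 rose and 0 fell against wild-type thymus, with a median of 1.35 (camera p = 2.50e-04, and p = 0.0459 with an estimated correlation), including Cth (2.37 ± 0.24), Atf5 (1.92 ± 0.46) and Ddit4 (1.85 ± 0.33). Of 17 tRNA synthetase genes 7 rose and 0 fell, with a median of 0.77 (p = 3.35e-04, and p = 0.0384 with an estimated correlation), Sars by 1.65 ± 0.18 and Yars by 1.41 ± 0.19. Against labelled transgenic thymus 6 and 5 rose, with p = 2.48e-05 and 8.43e-05 (0.0260 and 0.0676 with an estimated correlation), and between the thymus groups 0 of either list was called (p = 0.0690 and 0.432). Culture medium is a likely alternative source, and lines measured in fresh medium beside leukaemias taken directly from mice would separate these.

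Line 1 differed from lines 2 and 3 across several lists. Its Notch list had a median log2 difference of -0.46, at percentile 0.73 of 10000 random lists, but the test was prompted by members of that list and so decides nothing, and this was 1 of 20 lists looked at. Myc, a member of the same list, ran the other way (10.13 against 8.34 and 8.29). The double-positive thymocyte list differed by -1.44 at percentile 0, and glycolysis by 0.65 at percentile 99.98. The double-positive list holds Rag1 and Dntt, whose low values in line 1 had been seen, so its percentile decides nothing either. Random lists were drawn gene by gene, while genes of 1 list can vary together, which can make such percentiles too extreme. In cell lines against wild-type thymus the estimated correlation was 0.51 for the double-positive list and 0.45 for glycolysis. With 1 array of line 1 none of this can be told from the state of a single culture, and no cause was tested.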
